A study of Mus musculus
Mus musculus castaneus with 235 samples.

How the data were processed

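Single mouse embryos were flushed from the oviduct and lysed, and total RNA was fragmented by heat, tailed, copied with template switching, amplified and depleted of ribosomal RNA, per the labels' protocols. For the 4sU libraries late 2-cell embryos had been cultured with 90 uM 4sU and polyadenylated RNA was treated with iodoacetamide. The series held 235 samples in 45 groups, of which 188 were embryo RNA libraries, 32 were 4sU or control libraries, 13 were bisulfite libraries and 2 were embryonic stem cell libraries. The embryo is the replicate throughout.

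The authors deposited raw counts per gene for each embryo, and counts per gene assigned to the mus or the cas allele. Reads were trimmed with Trim Galore, aligned with STAR 2.7.10a to mm10 and counted with featureCounts 1.5.0-p1, per the submitters' processing notes. How reads were assigned to an allele, the gene annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes such as Xist and Tsix cannot be told apart. For the 4sU libraries the authors deposited total counts and counts with conversions, and for 7 labelled females of the Xist-knockout cross a table of converted counts by allele. The bisulfite libraries and the unlabelled libraries of the Xist-knockout cross were not analysed here.

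Samples were grouped by the stage, cross and sex of their labels, and designs, lists and alternatives were written before the data were examined. Of 581 pairs of libraries compared none were identical. The tables held 24421 genes, 1059 X-linked, 23302 autosomal, 50 Y-linked and 10 unplaced, placed by matching 23204 symbols (95.02%) to RefSeq genes of GRCm38.p6 and a further 1108 as synonyms. CPM were computed from the deposited counts and the total of each library.

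Total counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fits) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. Sex was tested within stage with cross as a covariate. Knockout and CM females were tested in a fit of all 4 groups of the stage, which also gave the sex-by-cross interaction. Stage transitions came from 1 fit per cross without a sex term, and the 4sU comparison had sex as a covariate. SE is the standard error of the fitted log2 fold change. DESeq2 1.42.0 and edgeR with DESeq2's size factors were run as alternatives. A gene with 0 counts in every library of a group has no fold given, and 3 counts are taken as the floor.

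For alleles by gene, edgeR was fitted to a pair of columns per embryo with the embryo as a block, a strain term where both crosses were present, the embryo's allelic total as library size, and genes with at least 10 allelic reads in at least 50% of embryos. Adjustment was separate for X-linked and autosomal genes. The paternal share of an embryo is paternal over paternal plus maternal allelic reads, summed over X-linked genes without Xist or over autosomal genes. Shares were compared by exact permutation, or by 100000 resamples where splits were too many, and X with autosomal shares by exact sign-flips. The X-to-autosome balance used genes with a mean of at least 5 CPM and a pseudocount of 1 CPM, with sex labels permuted within cross. Wilson 95% intervals and the floor of 3 counts cover counting error only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these steps.

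Gene lists were drawn up beforehand and tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and their members were counted and adjusted over the list alone. They comprised Y-linked genes (10 genes), the X-inactivation centre (14), escape genes (20), X-linked housekeeping genes (31), X-linked germ-cell and multicopy genes (44) and X-linked MAPK and pluripotency regulators (9). Imprinted lists held paternally expressed (30), non-canonical (20) and maternally expressed genes (28). Stage and lineage lists held 2-cell (40), oocyte (44), trophectoderm (23), inner cell mass and epiblast (21) and primitive endoderm genes (18). Others held ribosomal protein genes (41), p53 targets (20), Polycomb and DNA methylation genes (26), and markers of cumulus and granulosa cells (17), oviduct (11), sperm (12) and blood (11). Of 483 genes 463 were in the tables.

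Genes were named by a rule. Per total-count comparison these were the 10 genes per direction (5 per stage transition) with the largest fold among those past the threshold with at least 20 CPM in the higher group, leaving out gene models without a symbol, up to 4 members of each list by p, Xist, Tsix, up to 10 X-linked genes by p and Y-linked genes. Per allelic comparison these were up to 10 X-linked and 10 autosomal genes per direction and members of the imprinted, escape and X-inactivation centre lists.

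Each step was tested on simulated counts with 100 genes changed at a log2 fold change of 1 and 100 at 2. For female against male at the 8-cell stage 35 and 66 were recovered (4 false of 105 calls, 10592 genes), for knockout against wild-type early blastocysts 31 and 85 (2 of 118, 8902 genes), and for the early blastocyst interaction 5 and 52 (0 of 57, 8899 genes). For CM 4-cell to 8-cell 24 and 84 were recovered (4 of 112, 10580 genes), and for the 4sU comparison 0 and 5 (4 of 9, 11680 genes). For X-linked alleles in early blastocysts 15 and 19 of 20 were recovered with 0 false calls (68 genes).

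Alternatives covered the tool, size factors, low-count filter, allelic read minimum, crosses apart, placement of the 4 embryos with conflicting sex labels, replicate numbers as a block, and each library of small groups left out in turn. Added after the data were seen were fits without libraries whose values go against their labels, fits of the block's embryos without the block, the by-gene knockout allele test, the test of converted X counts, autosomal shares without Rpph1, the autosomal gene with the most allelic reads, and log2 odds for the differences between share changes.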

Results

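RNA was sequenced from 188 single mouse preimplantation embryos to follow how X-linked expression is balanced between the sexes and between the parental X chromosomes. The parents came from different inbred strains, so that reads over strain variants could be assigned to the maternal or paternal allele. In the MC cross a C57BL/6J mother was mated to a CAST/EiJ father. In CM a CAST/EiJ mother was mated to a C57BL/6J father. In the Xist-knockout cross a CAST/EiJ mother was mated to a 129S1/SvImJ father with a mutated Xist, the gene of the noncoding RNA that coats and silences the X chromosome it is made from. Daughters of that cross inherit the mutated gene on the paternal X, whereas sons inherit no paternal X and are labelled wild type.

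The MC embryos comprised 4 zygotes of unknown sex, 3 females and 3 males at the early 2-cell stage, 2 and 5 at the late 2-cell stage, and 6 and 11 at the 4-cell stage. They comprised 6 and 9 at the 8-cell stage, 5 and 3 at the 16-cell stage, and 5 and 6 early blastocysts. CM embryos comprised 5 females and 5 males at the late 2-cell stage, 5 and 3 at the 4-cell stage, 8 and 2 at the 8-cell stage, 7 and 7 at the 16-cell stage, and 5 and 8 early blastocysts. The Xist-knockout cross gave 6 females and 17 males at the late 2-cell stage, 6 and 7 at the 4-cell stage, 6 and 7 at the 8-cell stage, and 7 and 5 early blastocysts. The title and the sex label disagreed for 4 further embryos, 3 late 2-cell MC embryos and 1 8-cell CM embryo, which entered no comparison by sex. Total counts per embryo ran from 244016 to 3514661 (median 977594). They lay between 2760662 and 3514661 in zygotes, 2035173 and 2781558 at the early 2-cell stage, and 746109 and 2450221 at the late 2-cell stage. They lay between 464627 and 1575499 at the 4-cell stage, 562962 and 1389159 at the 8-cell stage, 486965 and 1356676 at the 16-cell stage, and 244016 and 1288187 in early blastocysts. Counts assigned to an allele made up 20.11% to 29.82% of the total, 54173 to 878199 per embryo, of which 697 to 16846 were X-linked apart from Xist.

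Xist (chromosome X, 103460373 to 103483233, GRCm38.p6) was measured in every library first, because it is the knockout's target. It had 0 counts in each of the 4 zygotes. In wild-type females it was nearly absent at the early 2-cell stage (1.56 ± 2.7 CPM, SD, n = 3) and reached 562 ± 405 CPM in MC (n = 6) and 567 ± 397 CPM in CM (n = 5) at the 4-cell stage. At the 8-cell stage it stood at 2629 ± 595 CPM in MC (n = 6) and 1652 ± 738 CPM in CM (n = 8). At the 16-cell stage it stood at 1979 ± 401 CPM (n = 5) and 2113 ± 792 CPM (n = 7). In early blastocysts it was at 2651 ± 390 CPM (n = 5) and 1637 ± 653 CPM (n = 5). At the late 2-cell stage it was 16.96 ± 6.07 CPM in MC females (n = 2) and 0.69 ± 0.70 CPM in CM females (n = 5). Females of the Xist-knockout cross had 15.1 ± 14.9 CPM (n = 6), 140 ± 76.0 CPM (n = 6), 222 ± 132 CPM (n = 6) and 103 ± 42.5 CPM (n = 7) from the late 2-cell stage to the early blastocyst. In 4-cell to early blastocyst wild-type females 93.5% to 98.0% of the allelic Xist reads were paternal, against 6 of 23 in the 2 late 2-cell MC females (26.1%, Wilson 95% interval 12.6 to 46.5). They were 103 of 104 in the 3 MC embryos of that stage with conflicting labels, 26 of 27 in late 2-cell knockout females and 9 of 9 in early 2-cell females. The extent of the deletion is not given in the sources used here, and the reads left in knockout females were also assigned to the paternal allele, 152 of the 156 in early blastocysts (97.4%, Wilson 95% interval 93.6 to 99.0).

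**Figure D1:**
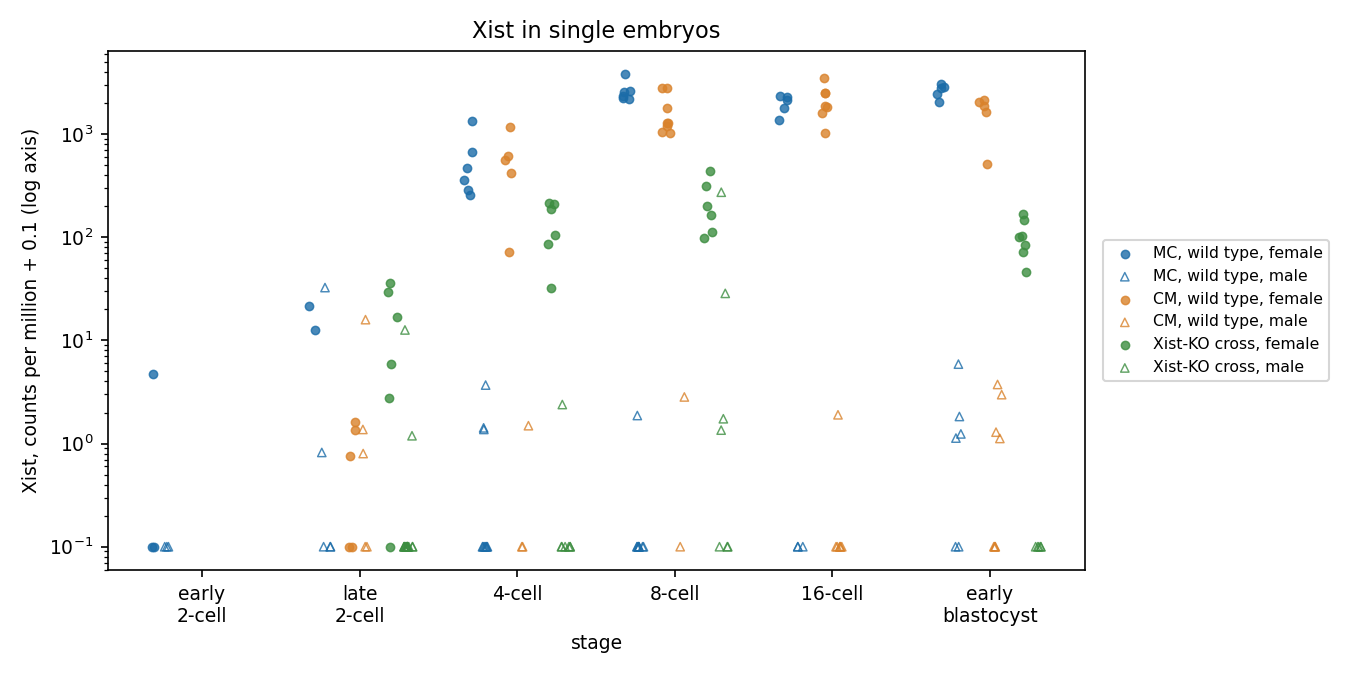
Xist level in CPM (vertical axis, log scale, after a small offset) in each embryo of known sex, by stage (horizontal axis), cross (colour) and sex (filled circles for females, open triangles for males). Each mark is 1 embryo, embryos without a count lie on the lowest line, and in early blastocyst females the means are 2651 CPM in MC, 1637 CPM in CM and 103 CPM in the Xist-knockout cross.

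The males' Xist level was at most 5.79 CPM with 5 exceptions. These were the libraries labelled 8-cell Xist-knockout-cross male 2 (273 CPM), late 2-cell MC male 5 (32.4 CPM), 8-cell Xist-knockout-cross male 12 (28.5 CPM), late 2-cell CM male 10 (15.8 CPM) and late 2-cell Xist-knockout-cross male 8 (12.5 CPM). Y-linked genes, carried by XY embryos, summed to at least 28.4 CPM in males from the late 2-cell stage on, except that the library labelled 8-cell Xist-knockout-cross male 2 had 0 Y-linked counts and a paternal X share of 49.7%. The library labelled 16-cell CM female 2 had 79.0 CPM of Y-linked genes beside 1016 CPM of Xist. In the 8-cell CM embryo with conflicting labels Xist stood at 2125 CPM and Y-linked genes at 0, and in the 3 late 2-cell MC embryos with conflicting labels Xist ran from 11.8 to 69.4 CPM with 0 Y-linked counts. All embryos kept the group of their labels.

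Wild-type females and males were compared at each stage to ask how X-linked transcript levels differ between XX and XY embryos. From the late 2-cell stage on, X-linked transcripts stood higher in females than in males, relative to autosomal transcripts. The X-to-autosome balance is the median over X-linked genes of the log2 level, centred for each gene, minus the same median over autosomal genes. Females stood at 0.33 ± 0.21 (SD, n = 7) and males at -0.26 ± 0.17 (n = 10) at the late 2-cell stage. They stood at 0.42 ± 0.12 (n = 11) and -0.37 ± 0.14 (n = 14) at the 4-cell stage, and 0.40 ± 0.20 (n = 14) and -0.35 ± 0.10 (n = 11) at the 8-cell stage. At the 16-cell stage the balance was 0.25 ± 0.20 in females (n = 12) and -0.30 ± 0.22 in males (n = 10), and in early blastocysts 0.23 ± 0.11 (n = 10) and -0.20 ± 0.10 (n = 14). Averaged over the crosses, females exceeded males by 0.54, 0.82, 0.74, 0.52 and 0.43 at these stages, with 7 of 7, 11 of 11, 14 of 14, 11 of 12 and 9 of 10 females above every male. Each difference passed a two-sided permutation test of sex within cross (adjusted p = 0.000227, 3e-05, 3e-05, 7.5e-05 and 4e-05, where 1e-05 is the smallest unadjusted p of the resampled tests). In early 2-cell embryos the difference was 0.17, with an exact permutation p of 0.1, the smallest that 3 against 3 embryos allow. Daughters of the Xist-knockout cross exceeded their brothers by 0.60, 0.79, 0.77 and 0.94 at the late 2-cell, 4-cell, 8-cell and early blastocyst stages, with all 25 daughters above every brother (adjusted permutation p = 4e-05, 0.00117, 0.00126 and 0.00126).

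**Figure D2:**
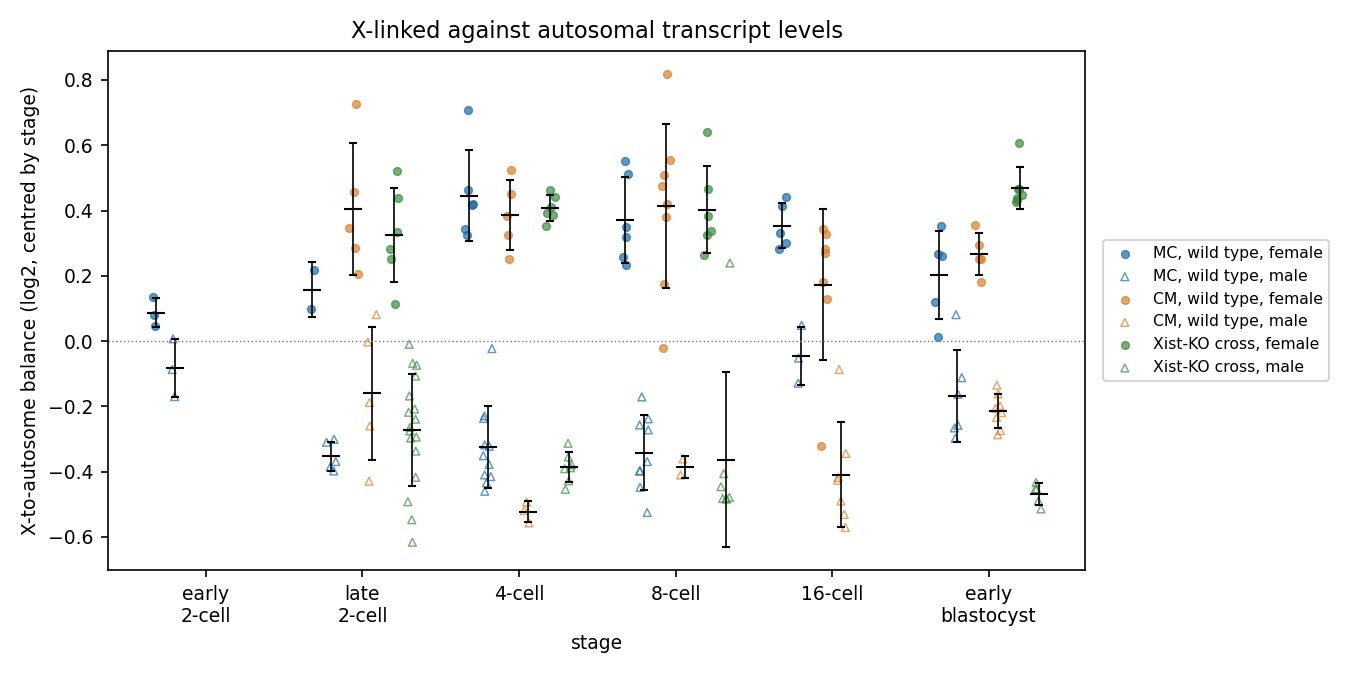
X-to-autosome balance (vertical axis, log2, centred within each stage) of each embryo by stage (horizontal axis), cross (colour) and sex (filled circles for females, open triangles for males). Black bars give the group mean and SD. The Xist-knockout cross was centred apart, so only sex differences compare, in early blastocysts 0.43 in wild type and 0.94 in that cross.

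Among single genes, those that differed by sex were mostly X-linked or Y-linked. Females had more of 37 genes and less of 5 at the 4-cell stage (of 11113 tested), 34 and 6 at the 8-cell stage (of 11255), 37 and 5 at the 16-cell stage (of 9420) and 21 and 6 in early blastocysts (of 9231). Of the genes higher in females 36, 33, 36 and 20 were X-linked, Xist included, with log2 fold changes of 9.77 ± 0.56 (SE), 12.20 ± 0.44, 12.84 ± 0.31 and 10.53 ± 0.33. Huwe1 (chromosome X, 151800785 to 151935417), a ubiquitin ligase, was higher by 1.05 ± 0.10, 0.83 ± 0.09 and 0.64 ± 0.09 from the 8-cell stage on. The list of X-linked housekeeping genes had 9 of 31, 11 of 31, 11 of 30 and 5 of 31 members higher in females (18, 18, 17 and 12 adjusted over the list alone). Among them was Uba1, the ubiquitin-activating enzyme, at 1.04 ± 0.12 in 8-cell embryos. Genes known to escape X inactivation in other mouse tissues had 3 of 13, 5 of 16, 4 of 13 and 3 of 13 members higher (7, 8, 9 and 10 adjusted over the list alone). Among them were the histone demethylase gene Kdm6a at 1.20 ± 0.26 in 8-cell embryos and 0.97 ± 0.18 in early blastocysts, and the RNA helicase gene Ddx3x at 0.87 ± 0.11 in 8-cell embryos. The X-inactivation centre had 1 of 4, 2 of 4, 2 of 4 and 2 of 5 members higher (2, 3, 2 and 2 adjusted over the list alone, with 1 lower at the 4-cell stage). Rhox5, a homeobox gene of the X-linked germ-cell and multicopy families, was at 0 in 8-cell males against 10.8 ± 10.8 CPM in females and differed by 6.84 ± 0.94 and 7.36 ± 0.58 at the next stages. That list had 1 of 7, 1 of 5 and 1 of 3 measured members higher at these stages (2, 3 and 1 adjusted over the list alone).

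Of the Y-linked genes 5 of 6, 5 of 6, 2 of 4 and 4 of 5 were lower in females from the 4-cell stage to the early blastocyst (6, 6, 3 and 5 adjusted over the list alone). Ddx3y, the Y-linked helicase gene, had 0 counts in 8-cell females against 62.9 ± 36.0 CPM in males. All X-linked genes apart from Xist, taken as a list, had 35 of 321, 32 of 357, 35 of 261 and 19 of 264 members higher at these stages (64, 73, 62 and 70 adjusted over the list alone, 1 lower at the 16-cell stage). The list stood above other genes by camera at each of these stages (adjusted p = 1.01e-37, 1.32e-26, 4.06e-22 and 8.32e-26). It did so too with an estimated correlation (adjusted p = 2.05e-09, 2.69e-07, 0.000171 and 3.35e-07), as did the X-linked housekeeping and escape lists. Among autosomal genes, Gata3, a trophectoderm regulator, was lower in 16-cell females by -0.83 ± 0.20, 1 of 19 trophectoderm genes measured there. The 9 X-linked MAPK and pluripotency regulators had 0 members past the threshold at any stage (1, 1 and 2 higher in 4-cell, 8-cell and early blastocyst females and 2 higher and 1 lower in 16-cell females adjusted over the list alone). They stood higher in early blastocysts by camera (adjusted p = 6.08e-06, and 0.000655 with an estimated correlation). Lower camera calls of trophectoderm genes at the 8-cell stage (adjusted p = 0.0195), p53 targets at the 16-cell stage (0.0229) and ribosomal protein genes in early blastocysts (1.24e-05) were lost (adjusted p = 0.201, 0.324 and 0.243 with an estimated correlation).

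At the late 2-cell stage the X-linked list already stood higher in females by camera (mean log2 fold change 0.51, adjusted p = 1.44e-13, and 0.000886 with an estimated correlation), though edgeR called 0 of its 393 members (2 adjusted over the list alone, 2 by DESeq2). The only gene past the threshold was Usp9y, a Y-linked deubiquitinase gene, at 0 in females and 33.9 ± 21.4 CPM in males. That count of 1 became 2 without the library labelled CM female 8 and 3 without the library labelled CM male 10, and DESeq2 called 4 genes higher and 4 lower. In early 2-cell embryos edgeR called 0 of 9006 genes (378 at an unadjusted p under 0.05, 1 by DESeq2). The camera calls of the X-linked and 2-cell lists there (adjusted p = 0.0155 for both) were lost (adjusted p = 0.44 and 0.587 with an estimated correlation). The sex difference did not differ between the MC and CM crosses for any gene by edgeR at the 5 stages with both crosses (457 to 605 genes at an unadjusted p under 0.05, no other tool run). In early blastocysts DESeq2 called 50 genes higher and 13 lower.

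The maternal X of females was compared with the single X of males by the log2 ratio of maternal X-linked to maternal autosomal allelic reads. It differed between the sexes by -0.04 to 0.31 in wild-type embryos and by -0.05 to 0.10 in the Xist-knockout cross, and passed no permutation test (lowest adjusted p = 0.708 and 0.419). The 0.31, in early blastocysts, became 0.04 without the library labelled CM male 8. With the median over genes the late 2-cell Xist-knockout cross passed at 0.18 (permutation, adjusted p = 0.0199), and the 16-cell and knockout early blastocyst signs turned (0.044 and 0.12). The sign turned without MC male 1 at the 16-cell stage (0.001), without male 2 at the early 2-cell stage (-0.006) and without CM female 5 at the late 2-cell stage (-0.017).

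Autosomal alleles came first, as background for the X. Transcripts were almost all maternal in zygotes and early 2-cell embryos and near parity from the 16-cell stage on. The paternal share of autosomal allelic reads was 1.54% ± 0.086 in zygotes (SD, n = 4) and 3.06% ± 0.119 in early 2-cell females (n = 3), and in MC females 24.2%, 36.1%, 47.3%, 51.0% and 52.2% from the late 2-cell stage to the early blastocyst. By gene, edgeR called 6828 of 6904 autosomal genes maternal in zygotes (median log2 paternal over maternal -6.29), 5431 of 5767 in early 2-cell embryos (-5.86), 2821 of 4489 in late 2-cell embryos (-2.37) and 1045 of 3931 in 4-cell embryos (-0.60). At the 8-cell stage 185 of 3843 genes were maternal and 59 paternal, at the 16-cell stage 15 and 38 of 3705, and in early blastocysts 18 and 61 of 4150. DESeq2 called 75 maternal and 84 paternal at the 16-cell stage, and 46 and 84 in early blastocysts. Maternal transcripts in zygotes included H1foo, the oocyte linker histone (-7.51 ± 0.29).

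Genes with non-canonical imprints, maternally silenced through histone H3K27me3, were mostly paternal from the late 2-cell stage on. Of the members measured, 2 of 2 were maternal in zygotes and in early 2-cell embryos, and 2 of 3 were paternal at the late 2-cell stage, 4 of 5 at the 4-cell and 8-cell stages, 5 of 6 at the 16-cell stage and 7 of 8 in early blastocysts. The counts were the same adjusted over the list alone, with 1 maternal member at the late 2-cell and 4-cell stages each. Epas1 (chromosome 17, 86753864 to 86833410), a hypoxia-inducible factor gene, was at 98.3% ± 1.8 paternal (SD) in 8-cell embryos with a log2 ratio of 5.93 ± 0.29. Gab1, a signalling adaptor, was at 98.8% ± 2.4 in 16-cell embryos, Sfmbt2, a Polycomb-group gene, at 97.7% ± 4.3, and Slc38a4, an amino acid transporter gene, at 91.7% ± 21.9 in early blastocysts, where the SDs include the library labelled CM male 8. Paternally expressed imprinted genes passed as paternal in 2 of 3, 1 of 2, 2 of 2 and 2 of 2 measured members from the 4-cell stage on (the same adjusted over the list alone). They were led by Kcnq1ot1, a noncoding RNA, at 96.9% ± 5.7, 97.0% ± 3.6, 96.3% ± 4.4 and 92.8% ± 19.5. Before the 4-cell stage all measured members of that list were maternal (4 of 4, 4 of 4 and 2 of 2), as were the maternally expressed imprinted genes (7 of 7, 6 of 6 and 2 of 2). The last included Igf2r at -2.07 ± 0.59 in late 2-cell embryos, and from the 4-cell stage on 0 of 1 passed.

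The paternal share of X-linked reads, Xist left out, was then followed in females to ask when the paternal X is silenced. It stood near the autosomal share up to the 4-cell stage and below it in 16-cell embryos and early blastocysts. In MC females it was 3.75% ± 0.224 at the early 2-cell stage (SD, n = 3), 26.6% ± 1.79 at the late 2-cell stage (n = 2), and 35.8% ± 3.25 at the 4-cell stage (n = 6). It was then 41.7% ± 3.63 at the 8-cell stage (n = 6), 31.7% ± 2.53 at the 16-cell stage (n = 5) and 24.3% ± 3.16 in early blastocysts (n = 5). In CM females it was 20.3% ± 12.8 (n = 5), 43.2% ± 1.85 (n = 5), 40.8% ± 4.57 (n = 8), 38.6% ± 2.17 (n = 7) and 30.96% ± 4.36 (n = 5) from the late 2-cell stage on. The autosomal share of these CM females was 16.4%, 38.7%, 43.9%, 49.5% and 46.8%, the first with the library labelled female 8, whose share of 3.31% lay apart from the other 9 late 2-cell CM embryos (12.2% to 33.01%). Males, which have no paternal X, gave a background of 0.74% to 6.58% in single libraries, apart from the libraries labelled late 2-cell CM male 10 (28.9%), 8-cell Xist-knockout-cross male 2 (49.7%) and early blastocyst CM male 8 (95.3%).

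**Figure D3:**
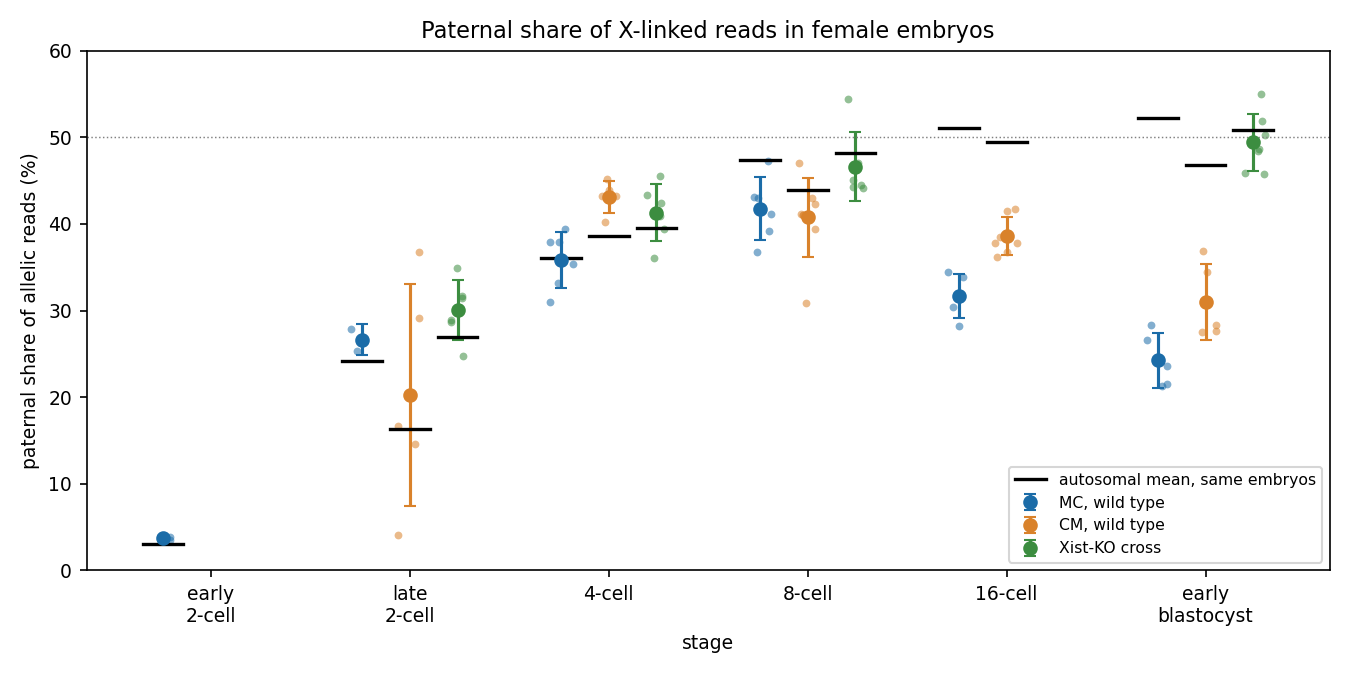
Paternal share of X-linked allelic reads without Xist (vertical axis, percent) in female embryos by stage (horizontal axis) and cross (colour). Small points are embryos, large points with bars are means and SD, and black lines are the mean autosomal shares of the same embryos; in early blastocysts the means are 24.3% in MC, 30.96% in CM and 49.4% in the Xist-knockout cross.

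Steps between consecutive stages were tested by two-sided exact permutation, adjusted over 12 comparisons. In MC females the share rose by 5.93 points to the 8-cell stage (adjusted p = 0.0297). It then fell by 10.1 points to the 16-cell stage (0.0173) and by 7.41 points to the early blastocyst (0.0297). With the median over genes the first and last of these did not pass (12.6 and -6.63 points, exact, adjusted p = 0.0831 and 0.143). In CM females it rose by 22.9 points to the 4-cell stage (exact, adjusted p = 0.0238). It fell by 7.65 points to the early blastocyst (0.0173, and 0.053 at -8.18 points with the median over genes). The steps of -2.40 and -2.14 points between the 4-cell and 16-cell stages passed no exact test (adjusted p = 0.326 and 0.321). The early MC steps of 22.9 and 9.19 points rested on 2 late 2-cell females and did not pass (adjusted p = 0.133, with an unadjusted exact p of 0.1 the smallest possible, and 0.0536). They passed at 20.2 and 11.9 points (exact, adjusted p = 0.0238 and 0.013) with the conflicting embryos placed by their Sex field. As log2 odds against the autosomal share of the same embryo, the MC step from the 4-cell to the 8-cell stage turned to -0.31 (adjusted exact p = 0.0436) and the CM step to the 4-cell stage to -0.094 (0.303). The CM steps to the 8-cell and 16-cell stages then passed at -0.46 and -0.45 (0.0317 and 0.0436), and the CM step to the early blastocyst did not at -0.34 (0.24). Against the autosomal share of the same embryos, the X share was lower in 6 of 6 MC (by -5.60 points) and 7 of 8 CM 8-cell females (-3.15 points, exact p = 0.102). It was lower in 5 of 5 and 7 of 7 MC and CM 16-cell females (-19.4 and -10.9 points), and 5 of 5 and 5 of 5 early blastocyst females (-27.9 and -15.8 points). None of these exact sign-flip tests passed after adjustment (lowest adjusted p = 0.117). Apart from CM at the 8-cell stage, each gave the smallest unadjusted p its embryos allow (0.0625 with 5, 0.0312 with 6 and 0.0156 with 7), so groups of 5 could not pass. Autosomal shares rest in part on Rpph1, the RNase P RNA gene on chromosome 14, with 7.15% of all autosomal allelic reads, and without it these differences were -4.43, -6.20, -16.8, -13.3, -24.9 and -19.4 points. The log2 odds of the MC and CM steps to the 8-cell stage were then -0.26 and -0.46 (exact, adjusted p = 0.0823 and 0.0317), those of the CM step to the 16-cell stage -0.42 (0.0541), and the CM step to the 4-cell stage passed downward at -0.25 (0.0476). The 4-cell to 8-cell change differed between CM and MC by -8.34 points. The 8-cell to 16-cell change differed by 7.94 points (permutation, adjusted p = 0.0113 for both). As log2 odds over the autosomal share these were -0.15 and 0.39 and did not pass (0.41 and 0.404). The earlier and later changes differed by 13.7 and -0.24 points and did not pass (permutation, adjusted p = 0.0888 and 0.925).

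By gene, X-linked alleles were tested in females of both wild-type crosses. Xist was the only gene called paternal from the 4-cell stage on, at 96.9% ± 2.1 paternal (SD over embryos), 94.8% ± 4.1, 94.3% ± 2.4 and 95.2% ± 1.1. The number of maternal genes grew from 12 of 91 at the 4-cell stage and 11 of 86 at the 8-cell stage to 33 of 74 at the 16-cell stage and 54 of 73 in early blastocysts. Rlim (chromosome X, 103957163 to 103981296), a ubiquitin ligase of the X-inactivation centre that activates Xist, was maternal at each of these stages, with log2 ratios of -1.43 ± 0.33, -3.96 ± 0.52, -3.86 ± 0.35 and -3.90 ± 0.35, and at the late 2-cell stage (-1.97 ± 0.74). With Xist it made up the 2 called members of the X-inactivation centre list, of 2 or 3 measured (the same adjusted over the list alone). The chromatin remodeller gene Atrx (chromosome X, 105797615 to 105929372) was at -1.33 ± 0.38 and -1.38 ± 0.32 at the 4-cell and 8-cell stages. In early blastocysts Msn (chromosome X, 96096045 to 96168553), which links actin to the membrane, was at 4.9% ± 12.2 paternal, Flna, an actin crosslinker gene, at 5.5% ± 4.6, and Hprt at 22.5% ± 15.4. X-linked housekeeping genes were maternal in 1 of 17, 3 of 16, 11 of 14 and 11 of 12 measured members from the 4-cell stage to the early blastocyst (the same adjusted over the list alone). Escape genes were maternal in 0 of 6, 1 of 7, 2 of 8 and 5 of 9 (3, 2, 1 and 4 adjusted over the list alone). Among these Ddx3x was maternal in early blastocysts (28.9% ± 9.4), Kdm5c was at 36.0% ± 16.5 (adjusted p = 0.046), and the values of Kdm6a (43.0% ± 18.4) and Ogt (47.3% ± 18.5) did not pass.

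At the 2-cell stages X-linked transcripts were mostly maternal, as autosomal ones were. Of 136 genes in early 2-cell females 106 were maternal and 1, Srpx2, was paternal (median log2 ratio -5.97, by DESeq2 112, 1 and -5.71). With MC only, parent and strain are not separated here or in zygotes. The 107 calls became 25, 42 and 49 without female 1, 4 and 5. In late 2-cell females 29 of 105 genes were maternal, among them Usp9x, a deubiquitinase gene (-5.04 ± 0.88). The count became 11 without MC female 8 and 19 without MC female 6. Housekeeping genes were maternal in 10 of 14 and 2 of 15 measured members at these stages, escape genes in 5 of 6 and 4 of 7, and germ-cell and multicopy genes in 1 of 1 and 0 of 1 (all the same adjusted over the list alone).

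Daughters of the Xist-mutant father were compared with CM daughters, which have the same maternal strain, to ask how loss of paternal Xist changes the paternal X. The paternal X share stayed near the autosomal share in knockout early blastocysts, where it stood at 49.4% ± 3.31 (SD, n = 7) against 30.96% ± 4.36 in CM females (n = 5). The difference of 18.5 points, with 7 of 7 knockout females above every wild-type female, passed a two-sided exact permutation test (adjusted p = 0.00505), and the autosomal share differed by 4.08 points (0.00253). As log2 odds against the autosomal share the difference was 0.90 (exact, adjusted p = 0.00505). At the 8-cell stage the shares were 46.6% ± 3.98 (n = 6) and 40.8% ± 4.57 (n = 8), a difference of 5.83 points (exact, adjusted p = 0.0226, 1 of 6 above every wild-type female) beside 4.24 points in autosomes (0.00133). That call was lost as log2 odds (0.10, adjusted p = 0.523), with the median over genes (8.90 points, 0.075), over shared genes (5.40 points, 0.0539) and without the 5 genes with the most reads (5.29 points, 0.143, all exact tests). At the 4-cell stage the difference was -1.86 points (exact, adjusted p = 0.292). At the late 2-cell stage it was 9.81 points (exact, adjusted p = 0.144, past the threshold at 13.9 points without CM female 1, and 0.292 at 5.76 points without CM female 8), beside 10.6 points in autosomes (0.0404), and -0.15 as log2 odds. Rpph1 was more paternal in knockout than in CM females at all 4 stages (exact, adjusted p = 0.00133 to 0.00379), by 25.6, 29.3, 16.5 and 8.46 points. Without it the autosomal differences were 10.3 (0.108), -2.07 (0.214), 1.26 (0.024) and 0.55 points (0.148, all exact), so the pooled ones rest largely on it at the 8-cell stage and in early blastocysts. The log2 odds were then 0.27 at the 8-cell stage (0.143) and 1.10 in early blastocysts (0.00505). The difference changed by 12.6 points between the 8-cell stage and the early blastocyst, by 7.69 points between the 4-cell and 8-cell stages and by -11.7 points between the late 2-cell and 4-cell stages (permutation, adjusted p = 0.00219, 0.0143 and 0.0373). As log2 odds the first passed (0.80, permutation, adjusted p = 0.00339) and the others did not (0.26 and -0.016, 0.244 and 0.887). The last was also -7.62 points (0.0965) without CM female 8, and follows the autosomal difference, which went from 10.6 to 0.845 points. Within the knockout cross the share rose by 11.2 points from the late 2-cell to the 4-cell stage and by 5.29 points to the 8-cell stage (exact, adjusted p = 0.0173 and 0.0297). It moved by 2.84 points to the early blastocyst (0.224). As log2 odds the first 2 steps turned to -0.11 and -0.20 (0.24 for both), and with the median over genes the second did not pass (4.95 points, 0.262).

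By gene, 7 of 89 X-linked genes carried a higher paternal share in knockout than in CM early blastocysts and 0 a lower one (DESeq2 14 and 0). This test was added after the data were seen. The paternal share of Msn was 70.6% against 8.8% with a log2 difference of 5.41 ± 1.06 (SE) and that of Flna 57.3% against 2.1%. It was 74.1% against 14.3% for the cohesin gene Smc1a, 43.2% against 2.9% for the kinesin gene Kif4 and 48.9% against 7.6% for the splicing factor gene Nono. Acsl4, a fatty acid ligase gene, stood at 50.9% against 3.0%, and the last of the 7 was Pnma5. Rlim stood at 12.7% against 5.6% and did not pass. Housekeeping genes passed in 3 of 15 measured members (4 adjusted over the list alone) and escape genes in 0 of 7 (0 adjusted over the list alone). At the late 2-cell, 4-cell and 8-cell stages edgeR called 0 of 104, 0 of 88 and 0 of 85 genes (6, 3 and 4 at an unadjusted p under 0.05, and 1, 0 and 0 by DESeq2). These counts became 1 without CM female 1 at the late 2-cell stage and 1 without CM female 4 at the 4-cell stage.

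In total counts, X-linked genes as a list stood higher in knockout early blastocysts. Of 263 X-linked genes other than Xist 19 were higher than in CM females and 0 lower (35 and 0 adjusted over the list alone, mean log2 fold change 0.49). The list stood above other genes by camera (adjusted p = 6.21e-16, and 3.12e-08 with an estimated correlation). Xist was lower by -3.99 ± 0.33. Atrx was higher by 0.98 ± 0.15 (676 ± 59.2 CPM against 340.4 ± 58.0 CPM), Usp9x by 0.72 ± 0.17, Nono by 0.98 ± 0.23, and Hprt, a purine salvage gene, by 0.75 ± 0.19. Housekeeping genes on the X were higher in 5 of 31 measured members (11 adjusted over the list alone, camera 7.39e-10, and 2.37e-06 with an estimated correlation). Escape genes were higher in 1 of 13 (3 adjusted over the list alone, camera 2.19e-05, and 0.000472 with an estimated correlation). In all, 55 genes were higher and 69 lower of 9153, and the 124 calls became 51 without CM female 11 and 55 without CM female 13 (20 X-linked calls became 9 and 11). DESeq2 called 106 higher and 117 lower. p53 targets fell in 2 of 17 measured members (6 adjusted over the list alone), the ubiquitin ligase gene Mdm2 by -1.50 ± 0.32 and Perp, a desmosomal gene, by -2.26 ± 0.50. The camera call of that list (adjusted p = 2.19e-05) was lost (adjusted p = 0.314 with an estimated correlation). Epas1, of the non-canonical imprinted genes, differed by -1.12 ± 0.27 and the ribosomal protein gene Rplp1 by -0.73 ± 0.20, each 1 of its list (of 13 and 41 measured). Several autosomal genes differed far more, such as Asxl3, a Polycomb-associated gene (24.6 ± 27.8 CPM against 4187 ± 3243 CPM), and Zic2, a zinc-finger gene (-4.40 ± 0.71).

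At earlier stages the knockout and CM females differed mostly in autosomal genes. At the 8-cell stage 66 genes were higher and 59 lower of 10395, with Xist at -2.89 ± 0.90 (adjusted p = 0.146). The 3 X-linked genes higher were the angiomotin gene Amot (1.89 ± 0.36), Acsl4 (0.78 ± 0.14) and Atrx (0.77 ± 0.18), and the count became 5 without either CM male 3 or 4. The pluripotency genes Nanog and Dppa5a were higher by 1.67 ± 0.42 and 0.64 ± 0.17 (2 of 19 inner cell mass and epiblast genes, 3 adjusted over the list alone). Igf2r was lower by -0.44 ± 0.11 (1 of 8 maternally expressed imprinted genes, 1 lower and 1 higher adjusted over the list alone). Housekeeping X genes were higher in 1 of 30 (3 adjusted over the list alone), and the list of all X-linked genes passed no camera test (median log2 fold change 0.09, mean -0.01, adjusted p = 0.666). At the 4-cell stage 15 genes were higher and 12 lower of 10781, with Xist at -2.05 ± 0.55 (adjusted p = 0.251). Of these 1 was X-linked, the phosphohydrolase gene Nudt11 (13.4 ± 9.45 CPM against 0), and that count became 0 without CM female 1, 2, 3 or 5. They included Asxl3, here higher (3369.9 ± 2484 CPM against 6.36 ± 4.36 CPM), Zic2 at -5.54 ± 0.65 and Foxp1, a forkhead gene, at -2.23 ± 0.38. At the late 2-cell stage 28 were higher and 9 lower of 10872, and the 37 calls became 140 without CM female 1 and 73 without CM female 2, with 2 and 1 X-linked where the whole set had 0. They included Pkdcc, a kinase gene, at 5.00 ± 0.69. DESeq2 called 104 higher and 97 lower at the 8-cell stage, 29 and 24 at the 4-cell stage, and 104 and 47 at the late 2-cell stage. There the camera calls of ribosomal protein genes (higher, adjusted p = 6.54e-09), oocyte transcripts (lower, 0.000436) and primitive endoderm genes (lower, 0.00531) were lost (adjusted p = 0.49, 0.523 and 0.259 with an estimated correlation).

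By their labels, sons of the knockout cross carry the same paternal strain without the mutation, and the sex-by-cross interaction sets the daughters against them. In early blastocysts 1 gene passed it, Atrx at 1.21 ± 0.21 (adjusted p = 0.00868). The count became 2 without Xist-knockout-cross male 8, and DESeq2 called 2. The X-linked list stood higher by camera (1 of 263 members, 8 adjusted over the list alone, adjusted p = 1.23e-09, and 2.3e-06 with an estimated correlation). Housekeeping X genes did so too (1 of 31, 3 adjusted over the list alone, 1.83e-06, and 6.09e-05 with an estimated correlation), as did escape genes (0 of 13, 0.00429, and 0.0103 with an estimated correlation). At the late 2-cell, 4-cell and 8-cell stages edgeR called 0 genes in the interaction (434, 512 and 579 at an unadjusted p under 0.05, and 1, 2 and 2 by DESeq2), though 2 passed at the 4-cell stage without CM male 7. Camera calls of the X-inactivation centre and ribosomal lists at the late 2-cell stage (0.00278 for both) and of oocyte and trophectoderm genes at the 8-cell stage (0.00492 and 0.011) were lost (adjusted p = 0.0545, 0.932, 0.723 and 0.517 with an estimated correlation).

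Stage transitions were followed to place the X chromosome within early development, in 1 fit of all embryos per cross (MC 12595 genes, CM 11004). From the zygote to the early 2-cell stage in MC, 1189 genes rose and 714 fell. The list of 2-cell (genome activation) genes rose in 24 of 33 measured members (26 adjusted over the list alone, mean log2 fold change 5.85, camera 1.38e-29, and 2.07e-07 with an estimated correlation). Zfp352, a zinc-finger gene of this wave, went from 0 to 124 ± 40.3 CPM (SD). H1foo fell (-3.52 ± 0.48). Ribosomal protein genes rose in 10 and fell in 18 of 41 (13 and 20 adjusted over the list alone, camera 0.00673, lost at adjusted p = 0.803 with an estimated correlation). To the late 2-cell stage 2880 rose and 2355 fell. Ribosomal protein genes rose in 37 of 41 (38 adjusted over the list alone, 1.16e-23, and 0.00313 with an estimated correlation). Oocyte transcripts fell in 31 of 40 (34 adjusted over the list alone, 1.9e-10, and 0.0119 with an estimated correlation). Inner cell mass and epiblast genes rose in 11 and fell in 3 of 21 (the same adjusted over the list alone, camera 0.0152, lost at adjusted p = 0.152 with an estimated correlation). Polycomb and DNA methylation genes fell in 14 and rose in 4 of 26 (15 and 4 adjusted over the list alone). With DESeq2's size factors the median of all genes moved from -0.13 to -0.24.

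From the late 2-cell to the 4-cell stage in MC 1691 genes rose and 2114 fell. Ribosomal protein genes rose in 38 of 41 (39 adjusted over the list alone, 3.14e-31, and 0.00037 with an estimated correlation). Oocyte transcripts fell in 20 of 40 (21 adjusted over the list alone) and 2-cell genes in 12 of 33 (the same adjusted over the list alone), Zfp352 by -2.97 ± 0.53. The camera calls of the last 2 lists (1.48e-06 and 0.00346) were lost (adjusted p = 0.1 and 0.355 with an estimated correlation). To the 8-cell stage 2375 rose and 3211 fell. Inner cell mass and epiblast genes rose in 12 of 21 (12 adjusted over the list alone, 1.19e-08, and 0.000401 with an estimated correlation), Pou5f1 by 2.98 ± 0.17. Trophectoderm genes rose in 15 of 23 (15 adjusted over the list alone, 7.67e-06, and 0.0017 with an estimated correlation). Ribosomal protein genes rose in 40 of 41 (41 adjusted over the list alone, 6.69e-25, and 0.00109 with an estimated correlation). Oocyte transcripts fell in 29 of 40 (30 adjusted over the list alone, 1.19e-08, and 0.0172 with an estimated correlation). Housekeeping X genes rose in 11 and fell in 4 of 31 (the same adjusted over the list alone, camera 0.0166, lost at adjusted p = 0.551 with an estimated correlation).

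From the 8-cell to the 16-cell stage in MC 1433 rose and 2004 fell, or 1764 and 1717 with DESeq2's size factors, which moved the median of all genes from 0 to 0.09. Trophectoderm genes rose in 13 of 23 (14 adjusted over the list alone, 1.3e-06, and 0.0014 with an estimated correlation), Gata3 by 4.68 ± 0.53. Oocyte transcripts fell in 27 of 40 (31 adjusted over the list alone, 7.31e-13, and 0.00297 with an estimated correlation), Btg4 by -6.43 ± 0.70. Primitive endoderm genes rose in 7 of 16, p53 targets in 7 of 19 and non-canonical imprinted genes in 4 of 15 (7, 7 and 4 adjusted over the list alone). Their camera calls (0.00726, 0.0178 and 0.0244) were lost (adjusted p = 0.134, 0.195 and 0.12 with an estimated correlation). From the 16-cell stage to the early blastocyst 638 rose and 640 fell, or 826 and 474 with DESeq2's size factors, which moved the median of all genes from 0.06 to 0.20. Trophectoderm genes rose in 9 of 23 (10 adjusted over the list alone, 5.2e-05, and 0.00678 with an estimated correlation). Primitive endoderm genes rose in 6 of 16 (7 adjusted over the list alone, 0.0258, lost at adjusted p = 0.294 with an estimated correlation). Lower camera calls of oocyte transcripts (6 of 40 fell, 7 adjusted over the list alone, 0.0258), ribosomal protein genes (0 of 41, 0.0303) and p53 targets (1 of 19, 0.0295) were lost (adjusted p = 0.499, 0.606 and 0.294 with an estimated correlation). All X-linked genes except Xist passed no camera test at any MC transition. There were 39 up and 9 down, 81 and 71, 35 and 71, 64 and 85, 47 and 41, and 17 and 24 of 394. These were 35 and 8, 80 and 71, 34 and 66, 62 and 83, 44 and 39, and 17 and 24 adjusted over the list alone.

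In CM, 3232 genes rose and 2025 fell from the late 2-cell to the 4-cell stage (2852 and 2451 with DESeq2's size factors, with the median of all genes moving from 0.23 to 0.03). 2-cell genes fell in 16 of 28 (18 adjusted over the list alone, 1.29e-09, and 0.00591 with an estimated correlation). Oocyte transcripts fell in 22 of 36 (22 adjusted over the list alone, 1.93e-09, and 0.0314 with an estimated correlation), Btg4 by -3.56 ± 0.55. Xist rose by 7.28 ± 1.86. Ribosomal protein genes rose in 39 of 41 there and in 37 of 41 to the 8-cell stage (39 and 41 adjusted over the list alone), and both camera calls (7.73e-16 and 3.22e-17) were lost (adjusted p = 0.175 and 0.138 with an estimated correlation). To the 8-cell stage 1046 rose and 1636 fell. Of 21 trophectoderm genes 11 rose (12 adjusted over the list alone, 1.84e-05, and 0.0185 with an estimated correlation). Of 20 inner cell mass and epiblast genes 9 rose, Pou5f1 by 1.86 ± 0.22 (9 adjusted over the list alone, 0.000222, and 0.0185 with an estimated correlation). To the 16-cell stage 586 rose and 1036 fell (753 and 818 with DESeq2's size factors, median of all genes -0.06 to 0.06). X-linked genes fell in 48 of 324 and rose in 2 (the same adjusted over the list alone, mean -0.59, camera 6.76e-05, lost at adjusted p = 0.392 with an estimated correlation). Atrx fell (-0.81 ± 0.16). Trophectoderm genes rose in 7 of 21 (9 adjusted over the list alone, 1.51e-06, and 0.0138 with an estimated correlation). Oocyte transcripts fell in 22 of 36 (26 adjusted over the list alone, 1.74e-10, and 0.0151 with an estimated correlation). To the early blastocyst 1419 rose and 1396 fell (1754 and 1121 with DESeq2's size factors, median 0.06 to 0.21). Trophectoderm genes rose in 11 of 21 (11 adjusted over the list alone, 3.22e-05, and 0.0264 with an estimated correlation). Primitive endoderm genes rose in 9 of 13 (10 adjusted over the list alone, 0.000188, and 0.0264 with an estimated correlation). Non-canonical imprinted genes rose in 6 of 15 (6 adjusted over the list alone, 0.00367, and 0.0299 with an estimated correlation). Markers of other cell types were barely measured, with 1 to 4 cumulus and granulosa, 0 to 3 oviduct, 1 to 3 sperm and 0 to 3 blood genes per comparison and no camera call (lowest adjusted p = 0.135).

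Labelling of new RNA with 4-thiouridine (4sU) was compared with no label in late 2-cell MC embryos, to ask whether it moves transcript levels. Labelled libraries (7 females and 5 males) held 12588245 to 15277389 counts and unlabelled ones (5 and 2) 8278904 to 13532961. With label 16 genes were higher and 130 lower of 12230, 8 of the latter X-linked, Usp9x among them (-1.07 ± 0.18), the 1 of 18 measured escape genes (2 adjusted over the list alone). Oocyte transcripts were higher in 5 of 40 (5 adjusted over the list alone, camera 3.57e-06, and 0.0126 with an estimated correlation), Nlrp14 by 1.45 ± 0.33 and Btg4 by 1.13 ± 0.23. Leaving out single libraries brought the 146 calls down to between 9 (without unlabelled male 1) and 82 (without unlabelled female 3), and the 8 X-linked calls to 2 to 6. DESeq2 called 346 higher and 561 lower, with the median of all genes at -0.28 against -0.04. Xist and Y-linked genes set the libraries labelled 4sU male 3 and male 7 apart (0.20 and 1.00 CPM of Y-linked genes). The libraries labelled male 8 and male 9 held both Xist (36.9 and 42.8 CPM) and Y-linked genes (46.7 and 98.4 CPM).

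In labelled MC embryos the X chromosome gave 4.21% ± 0.589 of the converted counts in females (SD, n = 7) and 2.97% ± 0.651 in males (n = 5), a difference of 1.23 points (exact permutation p = 0.0114). The test rests on the sex labels, which the Xist and Y-linked values above put in doubt for 4 of the 5 males. In total counts of the same libraries the difference was 0.90 points (exact p = 0.0013), and both tests were added after the data were seen. Converted counts by allele were given for 49 genes in 7 labelled females of the Xist-knockout cross, with 1201 to 9608 counts per embryo. The authors' table names gene groups Cat 1 (25 genes) and Cat 4 (24 genes), not defined in the sources used here. The paternal share of converted counts was 48.5% ± 34.3 in Cat 1 and 25.2% ± 14.6 in Cat 4 (SD, n = 7). Few genes carry the Cat 1 share, with 3 to 5 genes of at least 10 counts per embryo, gene medians of 9.09%, 5.26% and 0% in females 4, 5 and 6 (pooled 48.4%, 63.1% and 37.4%), and 495 of 1128 paternal counts from Rbbp7 in 1 embryo. It was higher in Cat 1 in 5 of 7 embryos, by 23.4 ± 24.2 points, and did not pass a two-sided exact sign-flip test (p = 0.0625, where 0.0156 is the smallest possible).

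**Figure D4:**
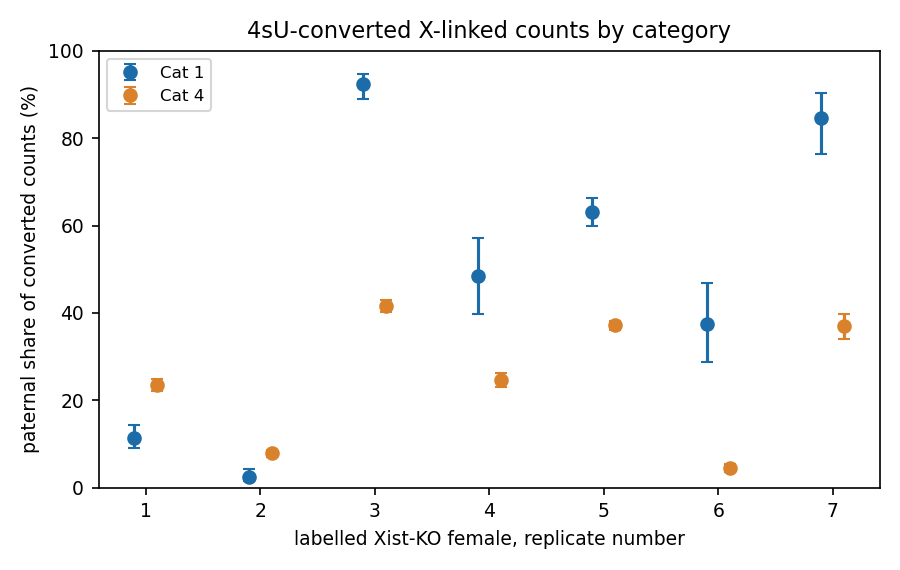
Paternal share of 4sU-converted X-linked counts (vertical axis, percent) in Cat 1 and Cat 4 genes of each labelled Xist-knockout female (horizontal axis, replicate number). Points are shares of summed counts, bars are Wilson 95% intervals that cover counting error only, and Cat 1 runs from 2.55% to 92.3% against 4.5% to 41.6% in Cat 4.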

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

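Tests chosen after the result was seen were the deletion and separate-set tests, the mixing test, the gap tests by distance from Xist, and the splits of the sex, knockout, interaction, stage and 4sU comparisons, of X alleles in early blastocysts, of autosomal alleles at the 4-cell and 8-cell stages and of knockout alleles in early blastocysts.

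A library far from the others of its group was found 24 times in 117 groups and measures, where chance flags about 1 in 20 groups (5.9). Paternal X shares apart from their groups were those of 16-cell CM male 7 (6.12%), 8-cell CM female 2 (30.9%) and 8-cell Xist-knockout-cross female 1 (54.4%). Others were the libraries labelled 8-cell Xist-knockout-cross male 2 (49.7%), early blastocyst CM male 8 (95.3%) and late 2-cell CM male 10 (28.9%). The autosomal paternal share set apart the library labelled 16-cell CM female 2 (62.4%, others 46.2% to 48.8%) and 4-cell Xist-knockout-cross male 6 (36.8%). X-to-autosome balance set apart the library labelled 16-cell CM female 2 (-0.32), 4-cell MC female 4 (0.71), the library labelled 8-cell Xist-knockout-cross male 2 (0.24) and early blastocyst Xist-knockout-cross female 3 (0.61). The maternal X ratio set apart 4-cell CM female 4 (-6.17), 4-cell MC female 4 (-5.23), the library labelled early blastocyst CM male 8 (-9.90) and early blastocyst Xist-knockout-cross male 1 (-5.45). Xist set apart 16-cell CM male 8 (1.80 CPM), 4-cell Xist-knockout-cross male 10 (2.29 CPM), the library labelled 8-cell Xist-knockout-cross male 2 (273 CPM) and 8-cell MC female 7 (3798 CPM). It also set apart 8-cell MC male 6 (1.77 CPM), early blastocyst MC male 2 (5.79 CPM), the library labelled late 2-cell CM male 10 (15.8 CPM) and late 2-cell MC male 5 (32.4 CPM).

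Differences between groups that passed a test were those of the knockout effect on the paternal X share between stages (-11.7, 7.69 and 12.6 points), of the change in share between CM and MC (-8.34 and 7.94 points), and of the sex difference of Atrx between the crosses (1.21). Of the share differences only the 12.6 passed as log2 odds too (0.80). A signal outside the comparisons was Xist in the embryonic stem cell libraries (26.1 and 22.2 CPM, 453 and 503 counts, above the floors of 0.173 and 0.133 CPM).

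Autosomal genes such as Cacna1s and Iglon5 were on in every embryo of one set of libraries and off in another set of the same stage. Of the autosomal genes called in knockout females at the late 2-cell and 4-cell stages 100% moved the same way in sons, which carry no mutation, by medians of log2 3.61 and 4.61 (3.87 and 4.63 in daughters), which argues against the deletion of Xist as the cause. At the 8-cell stage and in early blastocysts 83.1% did, by 0.95 and 0.62 (1.94 and 1.45 in daughters), so a part played by the deletion stays open there. Sets prepared apart cannot be told apart from a cross difference, with 30 such genes between MC and CM over 5 stages and 13 between the sexes over 14 sets. A cis difference between the fathers stays open too, with a median of 35.7% paternal reads over 3 genes that run from 2.9% to 98.8%, too few to decide.

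The autosomal paternal share ran from 3.31% in the library labelled female 8, which had the lowest 2-cell list level (3.847), to 33.01% among the 10 late 2-cell CM embryos. Embryos may lie at different points of genome activation, but the relation with the oocyte list was undecided (Pearson r = -0.479, permutation p = 0.159, rho = -0.636, p = 0.0537, r = -0.297 without the 2 farthest, adjusted p = 0.238 over 6 relations). So was that with the 2-cell list (r = -0.04, rho = -0.309, adjusted permutation p = 0.909), which was -0.812 without the 2 farthest. Depth was undecided too (r = -0.263, permutation p = 0.456, rho = -0.176, r = -0.232 without the 2 farthest, adjusted p = 0.548).

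In the library labelled early blastocyst CM male 8 the X reads carried the C57BL/6J allele. Paternally expressed imprinted genes gave 7.5% of their reads to the allele that the label makes paternal (70.3% to 96.0% in other CM males), which a library from the MC cross could give. Autosomal reads with the C57BL/6J allele stood at 48.95%, which argues against C57BL/6J RNA mixed in. No biological explanation was tested.

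Other splits of the same samples gave, as real calls against the highest of the others with the number of splits reaching the real one, 37 against 1, 27 against 0, 125 against 49 and 124 against 51 for knockout against wild-type females by stage (1 of 40 each). They gave 42 against 1, 40 against 2, 42 against 0 and 27 against 9 for sex from the 4-cell stage (1 of 40 each), so chance can be excluded there. For sex at the late 2-cell stage (1 against 1, 3 of 40) and the early blastocyst interaction (1 against 16, 3 of 40) other splits reached the real count, so chance stays open. With a real count of 0, as for the earlier interactions (0 against 1106, 0 against 2 and 0 against 25, 40 of 40), every split reaches it by construction, and chance is not excluded. The 1106 calls of another late 2-cell split point to a structure of the samples. For 4sU (146 against 4) and the stage pairs fitted alone (MC 3414 against 1, 4650 against 494, 2987 against 0, 3799 against 0, 2382 against 13 and 1869 against 2, CM 3698 against 0, 2051 against 151, 1616 against 1 and 3322 against 0) it can be excluded (1 of 24 each). For alleles it can be excluded on the X (29 against 0, 13 against 1, 12 against 0, 34 against 3 and 55 against 0 from the late 2-cell stage, and 7 against 2 for knockout early blastocysts, 1 of 24 each). Nor did any other split on autosomes (5453 against 0, 2840 against 638, 1090 against 0, 244 against 0, 53 against 0 and 79 against 0 from the early 2-cell stage, 1 of 22 each). For knockout alleles at the earlier stages the real count is 0 too, so every split reaches it and chance is not excluded (0 against 0, 0 against 1 and 0 against 1, 24 of 24). Splits were too few for sex at the early 2-cell stage (10 of 10), early 2-cell X alleles (1 of 4) and zygote alleles (1 of 8).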

How the results depend on the processing

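Fits without libraries whose values go against their labels, fits of the block's embryos without the block, autosomal shares without Rpph1 and the by-gene knockout allele test were chosen after the data were seen. Of 367 test values under other settings 323 kept their direction and side of the threshold, 16 lost the threshold, 6 gained it and 22 turned, and of 329 counts 234 stayed within 1.5 times. With single libraries left out 195 of 199 test values and 322 of 373 counts did so. The Atrx interaction kept its direction in all 15 settings. Unless stated, the cause was not tested. The minimum of 10 reads leaves 73 to 136 X-linked genes testable in wild-type females. The self-test shows that the 4sU comparison misses most changes of log2 1 or 2. The 4sU comparison of the Xist-knockout cross was not run because its unlabelled libraries were not used here, and CM in place of MC is the CM fit itself.

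With the median over genes, the share changes were 12.6 (MC 4-cell to 8-cell, adjusted p = 0.0831), -6.63 (MC to early blastocyst, 0.143), -8.18 (CM to early blastocyst, 0.053) and 4.95 points (knockout 4-cell to 8-cell, 0.262). The X minus autosomal difference of knockout early blastocysts turned to 1.03, and the 8-cell knockout difference was 8.90 (0.075). Without the escape and X-inactivation centre lists MC 4-cell to 8-cell was 5.55 (0.0552), and X minus autosomal in MC 4-cell females turned to 0.769. Without the 5 genes with the most reads MC 4-cell to 8-cell was 4.97 (0.107), knockout 4-cell to 8-cell 5.32 (0.0996) and the 8-cell knockout difference 5.29 (0.143). Over shared genes that difference was 5.40 (0.0539). These are exact permutation tests.

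As log2 odds over the autosomal share, which removes the autosomal rise by construction, the steps turned to -0.12 (MC early to late 2-cell), -0.20 (MC late 2-cell to 4-cell), -0.31 (MC 4-cell to 8-cell), -0.094 (CM late 2-cell to 4-cell), -0.11 (knockout late 2-cell to 4-cell) and -0.20 (knockout 4-cell to 8-cell), and the late 2-cell knockout difference to -0.15. CM 4-cell to 8-cell (-0.46) and 8-cell to 16-cell (-0.45) passed. CM to early blastocyst (-0.34) and the 8-cell knockout difference (0.10) did not. CM 16-cell odds include the library labelled female 2, which leaves both such steps open. With Rpph1 left out of the autosomal share, the log2 odds of the same steps were -0.15, -0.18, -0.26, -0.25 (adjusted p = 0.0476), -0.11 and -0.20. Those of the late 2-cell, 4-cell and 8-cell knockout differences were -0.12, 0.013 and 0.27 (not passed). CM 4-cell to 8-cell passed at -0.46, and CM 8-cell to 16-cell (-0.42, adjusted p = 0.0541) and CM to early blastocyst (-0.40) did not. X minus autosomal in MC 4-cell females turned to 0.045. With conflicting embryos placed by their Sex field the early MC steps passed at 20.2 and 11.9 points.

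The maternal X ratio turned to 0.044 (16-cell) and 0.12 (knockout early blastocyst) with the median over genes, where knockout late 2-cell passed at 0.18 (permutation, adjusted p = 0.0199), and to -0.021 (early 2-cell) and -0.015 (late 2-cell) without the 5 genes with the most reads.

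DESeq2 gave 151 genes (3 X-linked) for late 2-cell knockout, 53 at the 4-cell stage, 201 at the 8-cell stage and 223 in early blastocysts, and 1, 2, 2 and 2 (2 X-linked) for the interactions. For sex it gave 1 (early 2-cell), 8 with 2 X-linked (late 2-cell) and 63 with 36 X-linked (early blastocyst), and for 4sU 907 with 40 X-linked. For alleles it gave 457 (8-cell), 159 (16-cell) and 130 (early blastocyst) autosomal genes, 49, 21 and 20 X-linked genes at the late 2-cell, 4-cell and 8-cell stages, and 1 and 14 for knockout late 2-cell and early blastocyst.

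Without a low-count filter, which adds genes, knockout gave 46 genes with 2 X-linked (4-cell) and 241 with 10 X-linked (8-cell), while the interactions gave 14 (4-cell), 5 (8-cell) and 2 with 2 X-linked (early blastocyst). Sex gave 3 with 1 X-linked (late 2-cell), 68 (8-cell) and 66 (16-cell), and CM 8-cell to 16-cell 2463. With a mean of at least 5 CPM 4sU gave 45 with 3 X-linked.

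The female groups alone, with fewer embryos, gave 23 (late 2-cell), 0 X-linked (4-cell), 67 (8-cell) and 54 (early blastocyst) knockout calls. Sex-conflict embryos placed by the Sex field gave 3 and by title 0 late 2-cell sex calls, and leaving out the libraries that go against their labels gave 3 with 1 X-linked.

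With crosses apart, sex gave in MC and CM 0 and 0 (late 2-cell), 17 with 14 X-linked and 1 with 1 (4-cell), 19 with 16 and 11 with 7 (8-cell), 6 with 3 and 19 with 17 (16-cell), and 9 with 5 and 11 with 6 (early blastocyst). Autosomal alleles gave 670 (CM 4-cell), 129 and 347 (16-cell) and 301.0 and 353 (early blastocyst), and X alleles 5 and 46 (late 2-cell), 7 (MC 4-cell), 5 (MC 8-cell), 22 (CM 16-cell) and 34 (CM early blastocyst). Females only gave 128 autosomal genes at the 8-cell stage. At least 20 allelic reads gave 143 autosomal genes at the 8-cell stage and 8, 20 and 29 X-linked genes at the 4-cell, 16-cell and early blastocyst stages, and at least 5 reads gave 83 autosomal genes at the 16-cell stage.

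Samples share only a number, since at most 1 of 10 pairs of same-numbered embryos in a comparison correlated over 0.1 (0.118). With the replicate block the knockout share differences were 4.39 (8-cell, exact p = 0.375, 0.125 the smallest) and 16.4 points (early blastocyst, exact p = 0.25, the smallest), knockout calls 12 with 1 X-linked and 7 with 1, and 4sU calls 12 with 0. The same embryos without the block gave 23 with 1, 10 with 1 and 5 with 0. With the block the stage counts stayed within 1.5 times. No paired analysis was possible because late 2-cell and 4-cell knockout and CM females share fewer than 2 numbers.

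Left-out libraries moved the late 2-cell knockout share difference from 5.76 to 13.9, and the maternal X ratio from -0.006 to 0.23 (early 2-cell), -0.017 to 0.071 (late 2-cell) and -0.035 to 0.001 (16-cell). Knockout calls ran from 26 to 140 with 0 to 2 X-linked (late 2-cell), X-linked from 0 to 1 (4-cell) and 5 to 5 (8-cell), and 51 to 154 with 9 to 23 (early blastocyst). Interactions ran from 0 to 2 (4-cell) and 1 to 2 with 1 to 2 X-linked (early blastocyst), late 2-cell sex from 1 to 3 with 0 to 1, and 4sU from 9 to 82 with 2 to 6. X alleles ran from 25 to 49 (early 2-cell) and 11 to 33 (late 2-cell), and knockout alleles from 0 to 1 at the late 2-cell and 4-cell stages.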

Other observations

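The tests by distance from Xist within a stage were written before their results were seen, and the gap tests after. X-linked genes near Xist were less paternal than genes far from it in wild-type females from the 8-cell stage on. Genes within 10 Mb of Xist were at 33.2% paternal (18 genes) and others at 42.8% (67) at the 8-cell stage, 24.7% (15) and 38.3% (58) at the 16-cell stage, and 19.3% (15) and 29.8% (57) in early blastocysts. That silencing reaches genes near Xist first might explain this, and the Spearman rho of share and distance was 0.438, 0.459 and 0.436 (permutation, adjusted p = 0.00028, 0.00031 and 0.0004 over 7 relations, Pearson r = 0.399, 0.470 and 0.445). Genes are not independent replicates. At the 4-cell stage rho was -0.017, and in knockout females it was 0.037, 0.153 and 0.238 at the 4-cell, 8-cell and early blastocyst stages (permutation, adjusted p = 0.850, 0.230 and 0.0802).

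Per embryo, the gap between far and near genes was 17.98 ± 3.90 points in CM early blastocysts (SD, n = 5) and 3.64 ± 8.07 in knockout ones (n = 7), a difference of 14.33 (exact permutation p = 0.00126, adjusted p = 0.00379). At the 8-cell stage the gap was 11.99 and 8.51 ± 9.51 (above 0 in 5 of 6 knockout females), a difference of 3.48 (exact p = 0.405). At the 4-cell stage it was 4.14 (above 0 in 5 of 5 CM females) and -0.40, a difference of 4.55 (exact p = 0.193). The need for Xist on the paternal X may hold for the gap in early blastocysts, though the paternal X also differs in strain, and stays undecided at the earlier stages.

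The embryonic stem cell libraries, in no comparison, had Tsix at 69.0 and 69.7 CPM, Nanog at 1254 and 1183 CPM, Pou5f1 at 561 and 550 CPM, and the trophectoderm gene Cdx2 at 0.17 and 0.66 CPM.

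In late 2-cell embryos of the Xist-knockout cross (23 embryos) the autosomal paternal share fell with the oocyte list level (r = -0.908, rho = -0.885, r = -0.879 without the 2 farthest, permutation, adjusted p = 3e-05 over 6 relations). It fell too with the 2-cell list level (r = -0.855, rho = -0.901, r = -0.801 without the 2 farthest, adjusted p = 3e-05) and the log2 total count (r = -0.513, rho = -0.375, r = -0.473 without the 2 farthest, adjusted p = 0.0242), and these were not separated.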
